A study of Mus musculus with 31 samples.

How the data were processed

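RNA from the uterus of mice was measured on 31 arrays, 1 per sample, in 8 groups: wild-type (WT) and homozygous mutant (KO) mice of the AF2 and MISS lines, each given placebo or 17β-estradiol (E2). Per the labels, mice were ovariectomised at 4 weeks of age, rested for 3 weeks, and killed 6 h after a subcutaneous injection of castor oil with 0 or 8 µg/kg of E2. Each group holds 4 arrays except AF2 KO E2, which holds 3. The labels give the AF2 line on C57BL6/J and the MISS line on C57BL6/N. From knowledge outside the labels, the AF2 mutant makes an estrogen receptor α without activation function 2, and the MISS mutant makes one that cannot be palmitoylated and is missing from the membrane. No paired analysis of mice was possible because replicate numbers follow the order of deposition. Slides enter as a block and in values within each slide.

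The authors hybridised the samples to 1-colour (Cy3) Agilent arrays and extracted them with Agilent Feature Extraction 10.10.1.1. Per the file headers, the processed signal of each spot is an intensity with background subtracted and spatial trend removed, and with a surrogate in place of dim spots. It was not normalized between arrays. Per the file headers, each spot also carries 0/1 values for outliers, for saturation and for a signal well above background. The deposited series matrix of the authors holds log2 values of 43753 probes on 31 arrays, with 83 empty cells. Its columns have equal medians of 7.56, and each correlates at 0.999 or more across probes with the log2 median pixel signal of its own array. Centred on the mean of each probe, it correlated best with its own array for 31 of 31 arrays. The labels of the authors also name limma, without a version or a step.

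The analysis started from the processed signal. Each array holds 62976 spots, of which 59305 are not controls, for 55681 probes. Spots with an outlier mark were set missing, spots of the same probe were averaged on the log2 scale, and the 75th percentile of its array was subtracted from each value. All levels below are therefore log2 values relative to that percentile. A probe was tested if it was well above background on every array of at least 1 group, which kept 40332 probes. A gene was represented by its tested probe with the highest mean level, which gave 27056 genes, 3927 of them lincRNA features. Of these genes, 18808 had 1 tested probe and 8248 had more, up to 10. Probes carry gene names of the array annotation, and 27235 were named through their accession in a gene table, which changed 2838 names. That step was not part of the plan. Probe positions are those of the array annotation on mm9. Among the tested genes, 56 values were missing.

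A linear model per gene was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each of the 8 groups over all 31 arrays and 23 residual degrees of freedom, to which the prior added 2.38. There were 10 contrasts: E2 against placebo in each genotype of each line, KO minus WT of these responses within each line, MISS WT minus AF2 WT of these responses, and KO against WT and MISS WT against AF2 WT under placebo. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the contrast, with no minimum fold. Changes are given as log2 fold change ± standard error (SE) of the limma model, and group levels as mean and standard deviation (SD). Where a probe was well above background on no array of the dimmer group, the fold is given as "at least". It is then computed against the dimmest well-above-background signal of each array of that group, or the measured value where that was higher. With 3 or 4 arrays per group, the number of arrays limits the precision.

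A response score measured how much of the E2 response was left in each mutant. It is the mean level of genes raised by E2 minus the mean of genes lowered, less the mean of the placebo arrays of that genotype. The genes were those called with at least a 2-fold change in the wild type of the other line, so that they were not chosen on the arrays scored. KO and WT E2 arrays were compared by exact two-sided permutation. It exchanged the E2 arrays alone, after the placebo means were subtracted and without regard to slide. Its p therefore leaves out the spread of the placebo arrays. The 2-fold limits of the difference between 2 responses were judged by 95% confidence intervals.

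There were 26 lists of genes: estrogen-induced uterine genes, immediate early genes, DNA replication, mitosis, ribosome biogenesis, tRNA synthetases, endoplasmic reticulum (ER) chaperones, cholesterol synthesis, vascular factors, cytokines, steroid receptors and cofactors, Wnt pathway, progesterone targets, water and ion transport, matrix remodelling, interferon response, and markers of epithelium, stroma, smooth muscle, endothelium, macrophages, granulocytes, lymphocytes, adipocytes, ovary and oviduct, and bladder, skeletal muscle and blood. Each was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a contrast, and again with an estimated correlation. Members were also counted with p adjusted over the list alone. Named genes follow a fixed rule. For each E2 contrast these are the 10 called genes with the largest increase and the 5 with the largest decrease, with a mouse-style symbol and every E2 array on the same side of every placebo array. For the other contrasts they are the 5 largest each way. For each list they are the 4 members with the smallest adjusted p. Esr1, Pgr, Greb1, Igf1, Areg, Cdkn1a, Ltf, C3 and Nnt were always included. Some genes that this rule names are not reported here. Areg was not tested, because its probe was not well above background on every array of any group. Groups, contrasts, the tests described so far, lists, naming rule and all alternatives except the 2 described as added were chosen before the data were examined. Some tests of explanations for single results were chosen after those results were seen and are marked below.

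The method was tested on simulated arrays of 27056 genes, drawn as normal noise with the mean and residual SD of each real gene, in 5 runs per contrast with 200 genes changed in each. For E2 against placebo it called 36 to 45.2% of genes changed by 1.5-fold, 67.7 to 74.3% of those changed 2-fold and 92.8 to 95.5% of those changed 4-fold. For differences between responses these shares were 17.4 to 21.7%, 45.4 to 59.6% and 84.4 to 86.5%, and for genotypes or lines under placebo 40.7 to 42.4%, 69.3 to 74.2% and 94.7 to 96.1%. The share of false calls was 4.39 to 5.85%. A simulated loss of 50% of the response was read as 50.1 and 49.8% retained. In a further simulation the ER chaperones were raised 2-fold, and camera called that list and 0 others. Simulated genes varied independently and without a slide effect. The share of false calls and the camera result therefore need not hold for the real arrays.

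The alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited matrix, no filter or a strict filter on dim probes, slide as a block, a fit of the compared groups alone, a minimum of 2-fold, a variance prior with trend and robust settings, array weights, the mean of a gene's probes, other gene choices for the score, and each array left out in turn. Added after seeing the data were a fit without genes whose mean level lies under −2, and a fit with the array's median over the chemosensory receptor families as a covariate. The 31 arrays come from 4 slides, each with 1 array of every group, except that slide 2 holds no AF2 KO E2 array. Each slide has 1 scan, so slide and scan are the same factor. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with the R package data.table (version 1.17.8).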

Results

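Uterine RNA was profiled on 31 arrays from ovariectomised mice, 6 h after placebo or 8 µg/kg of E2. The AF2 line carries an estrogen receptor α (ERα, gene Esr1) that lacks activation function 2, the part of the receptor that recruits coactivators when hormone binds. The MISS line carries an ERα that acts in the nucleus but is missing from the cell membrane. Each of the 8 groups had 4 arrays, except AF2 KO E2 with 3. The 75th percentile of the processed signal was 531.8 to 1033 intensity units per array, 62.7 to 77.6% of probes were well above background, and 0 spots were saturated. The number of arrays limits the precision.

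The first principal component held 59.8% of the variance over the 27056 genes. Along it, AF2 WT E2 arrays lay at 92.5 to 103, MISS WT E2 arrays at 106 to 122 and MISS KO E2 arrays at 94.7 to 104. The AF2 KO E2 arrays lay at −73.2 to −63.9, beside the placebo arrays of all genotypes at −73 to −55.6. The second component held 9.96% and the third 6.11%, and the slide accounted for 84.2% of the third. On the second component the AF2 KO E2 arrays lay at 38.2 to 75.5, apart from AF2 KO placebo arrays at −7.79 to 13.8. AF2 WT placebo arrays lay there at 4.25 to 57.3.

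**Figure D1:**
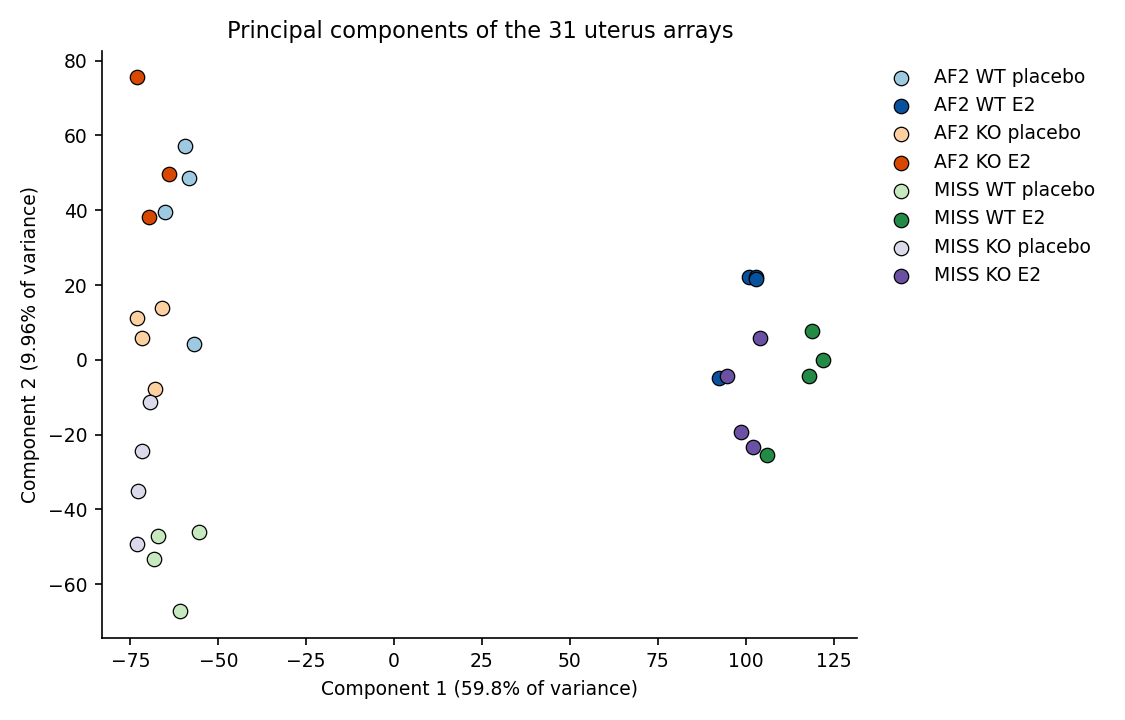
Position of each of the 31 arrays on the first and second principal components of the 27056 genes, by group, with the share of variance on each axis. The 3 AF2 KO E2 arrays lie at −73.2 to −63.9 on the first component, beside the placebo arrays, and the AF2 WT E2 arrays at 92.5 to 103. On the second component AF2 KO E2 arrays lie at 38.2 to 75.5 and AF2 KO placebo arrays at −7.79 to 13.8.

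Esr1 is the targeted gene of both lines, and its mRNA was detected in every group. The brightest Esr1 probe (chromosome 10, 5343056 to 5343115, mm9) had a level of 3.42 ± 0.13 (SD, n = 4) in AF2 WT placebo and 2.95 ± 0.08 (SD, n = 4) in AF2 KO placebo, a difference of −0.47 ± 0.12 (SE), adjusted p = 0.0147. A further probe, at 5379218 to 5379277, was lower in AF2 KO by −1.75 ± 0.14 (SE), adjusted p = 1.25e-08 over 40332 probes. The other tested Esr1 probes, at 5345046 to 5345105 and at 5489352 to 5489411, differed by −0.13 ± 0.23 and 0.21 ± 0.10 (SE), neither called, so the Esr1 probes disagree. In the MISS line the brightest probe differed by 0.05 ± 0.12 between KO and WT placebo and the probe at 5379218 by −0.00 ± 0.14 (SE). The files do not give the altered positions, so these probes check no genotype.

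Estradiol changed most of the tested genes in AF2 WT mice. Gdf15, a stress-induced member of the TGF-β family (probe on chromosome 8, 73153293 to 73153352), had the largest increase, 512-fold with an SE of 0.29 on the log2 scale (n = 4 and 4). Next, as log2 fold changes, were the keratin Krt87 with 8.04 ± 0.27, Trim15 with 6.90 ± 0.40, the small proline-rich protein Sprr2f with 6.89 ± 0.96, and the aggrecan-cleaving protease Adamts4 with 6.72 ± 0.29. Scube1, Mthfd2, Myh7 and Chac1 rose by 6.68, 6.51, 6.44 and 6.37, and Fgf21, an endocrine growth factor, rose at least 21.8-fold from a level not above background. Large decreases were in the sulfotransferase Chst9 with −5.94 ± 0.36, the tight junction gene Cldn1 with −5.24, Cyp1b1 with −4.83 and Pik3ip1 with −4.80. Known ERα targets rose, with 2.43 ± 0.11 for the progesterone receptor gene Pgr, 4.34 ± 0.45 for Greb1, 2.87 ± 0.13 for Igf1 and 4.23 ± 0.18 for Cdkn1a. Ltf and C3, secretory genes that rise with longer E2 exposure, gave 0.12 ± 0.46 and 0.10 ± 0.24 and were not called. In total 15597 of 27056 tested genes were called, 7466 higher and 8131 lower, with 6896 at 2-fold or more. Without the filter on dim probes 15816 of 35019 genes were called.

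Genes of 8 functional lists mostly rose with E2 in AF2 WT, and 3 of the lists were called by both forms of the test. All 24 measured genes of ribosome biogenesis rose (24 adjusted over the list alone), with a median of 2.20 and adjusted p = 3.14e-19, among them Rrp12 with 3.89, Nop58 with 2.87 and Gnl3 with 2.53. Of 20 tRNA synthetases 19 rose (19 adjusted over the list alone), with a median of 1.76 and adjusted p = 1.23e-12, and Tars rose by 2.86. Of 28 estrogen-induced uterine genes 23 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 2.51 and adjusted p = 4.68e-10. These 3 calls held with an estimated correlation, at adjusted p = 0.00582, 0.00438 and 0.0074. Of 18 immediate early genes 17 rose, with a median of 2.27 and adjusted p = 5.66e-07, but adjusted p = 0.143 with an estimated correlation. Of 20 ER chaperones 17 rose, with a median of 1.08 and adjusted p = 4.71e-07 (adjusted p = 0.112 with an estimated correlation), including Atf4 with 2.91 and Hspa5 with 1.91. Of 18 genes of cholesterol synthesis 16 rose, with a median of 1.88 and adjusted p = 5.94e-09 (adjusted p = 0.145 with an estimated correlation), including Cyp51 with 3.29 and Sqle with 3.08. Counts adjusted over the list alone were also 17, 17 and 16. Of 19 cytokines 12 rose and 2 fell (12 and 2 adjusted over the list alone), led by Il11 with 3.82 and Cxcl1 with 3.80, with adjusted p = 0.00663 and adjusted p = 0.333 with an estimated correlation. Of 18 genes of water and ion transport 10 rose and 2 fell (10 and 2 adjusted over the list alone), with adjusted p = 0.0362 and adjusted p = 0.396 with an estimated correlation, and the aquaporin genes Aqp8 and Aqp5 rose by 5.77 and 4.58. Within each of the 4 slides the medians of all 8 groups kept their sign, for example 2.12, 2.36, 2.21 and 2.15 for ribosome biogenesis.

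Fewer lists fell, and most markers of cell types were not called as lists. Of 15 stroma markers 12 fell and 1 rose (13 and 1 adjusted over the list alone), among them Lum with −1.85 and Pdgfra with −1.30, and the list median was −0.90 with adjusted p = 0.0013 and adjusted p = 0.145 with an estimated correlation. Of 18 interferon-response genes 11 fell and 2 rose (11 and 2 adjusted over the list alone), including Ifit2 with −2.41 and Ifit3 with −2.03, with adjusted p = 0.0175 and adjusted p = 0.794 with an estimated correlation. Of 17 epithelium markers 8 rose and 2 fell, with adjusted p = 0.232. Of 14 smooth muscle markers 1 rose and 3 fell, with adjusted p = 0.88. Of 15 endothelium markers 6 rose, such as Eng with 2.53 and Nos3 with 2.35, and 2 fell, with adjusted p = 0.449. Markers of immune cells were called 3 higher and 4 lower of 12 for macrophages (adjusted p = 0.834), 2 and 4 of 12 for granulocytes (0.88) and 1 and 2 of 15 for lymphocytes (0.834). None of 10 adipocyte markers was called (adjusted p = 0.967, with 0 also when adjusted over the list alone). Of 7 markers of ovary and oviduct 1 rose and 1 fell (0.834), and of 10 of bladder, skeletal muscle and blood 2 rose and 2 fell (0.88).

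The response to E2 in AF2 KO mice asks what is left of the hormone's action without activation function 2. Of the classical targets, Pgr gave −0.32 ± 0.12, Greb1 0.85 ± 0.48 and Cdkn1a 0.38 ± 0.19 (SE, n = 3 and 4), none of them called. Igf1 fell by 0.74 ± 0.14, from a level of 1.39 to 0.65, adjusted p = 0.00258. Stromal and matrix genes also fell, with −1.05 ± 0.26 for the collagen gene Col1a2, −0.76 ± 0.20 for Lum, −0.65 ± 0.16 for Col6a1, −0.86 ± 0.16 for the protease Mmp2 and −1.19 ± 0.32 for the cross-linking enzyme Loxl2. Other genes with large decreases were Dscaml1 with −1.92 (adjusted p = 0.0449), Angpt4 with −1.54, Pycr1 with −1.31, Frzb with −1.30 and Pcdh10 with −1.24, and with a strict filter on dim probes Pycr1, then read by another probe, gave 0.08. Of the 15 stroma markers 3 fell (5 adjusted over the list alone), median −0.14 and adjusted p = 0.000158, and of 20 matrix remodelling genes 2 fell (3 adjusted over the list alone), median −0.22 and adjusted p = 0.00556. Both calls were lost, at adjusted p = 0.297 and adjusted p = 0.483 with an estimated correlation. So were those of smooth muscle markers (median −0.38, 0 called), endothelium markers (median −0.10, 1 fell) and interferon-response genes (median 0.45, 0 called), at adjusted p = 5.66e-05, 0.00418 and 0.0059 and, with an estimated correlation, adjusted p = 0.483, 0.483 and 0.822.

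Most genes called with E2 in AF2 KO were dim and rose. Of 996 genes called, 846 were higher and 150 lower, and 600 of the higher ones had a mean level under −2. The largest increases were in Olfr911-ps1, Slc22a22, Atp13a4 and Tmc1, at least 5.8-, 4.59-, 5.83- and 5.92-fold, and in Slco6b1 with 3.70 ± 0.61 (SE). Btbd35f7, Vmn1r157, Nlrp4e, Sox3 and Gad2, genes known from germ cells, sensory or neural tissue, rose at least 2.32-, 2.46-, 2.86-, 2.14- and 2.46-fold. Chemosensory receptor families, chosen after their values were seen, had 56 genes called higher and 0 lower of 364 tested, with medians of 0.45, and of 0.31, 0.18 and 0.09 under the other scalings. Their median level per array was −4.20 ± 0.26 (SD, n = 3) in AF2 KO E2, −4.72 ± 0.08 in AF2 KO placebo and −4.29 ± 0.22 in AF2 WT placebo (SD, n = 4). With slide as a block 2770 genes were called, 2149 higher and 621 lower, and the 996 were among them. With quantile normalization 459 were higher and 184 lower. With the chemosensory level as an added covariate 327 were called, 191 higher and 136 lower, of which 127 were among the 996. That level ran from −4.41 to −3.91 in AF2 KO E2 and from −4.78 to −4.61 in AF2 KO placebo. It thus separates the compared groups and includes called genes, so fewer calls with it follow in part by construction. The count fell to 239 without AF2 KO E2 replicate 1, 584 without AF2 KO E2 replicate 2, and 560, 555 and 625 without AF2 KO placebo replicates 1, 2 and 4.

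**Figure D2:**
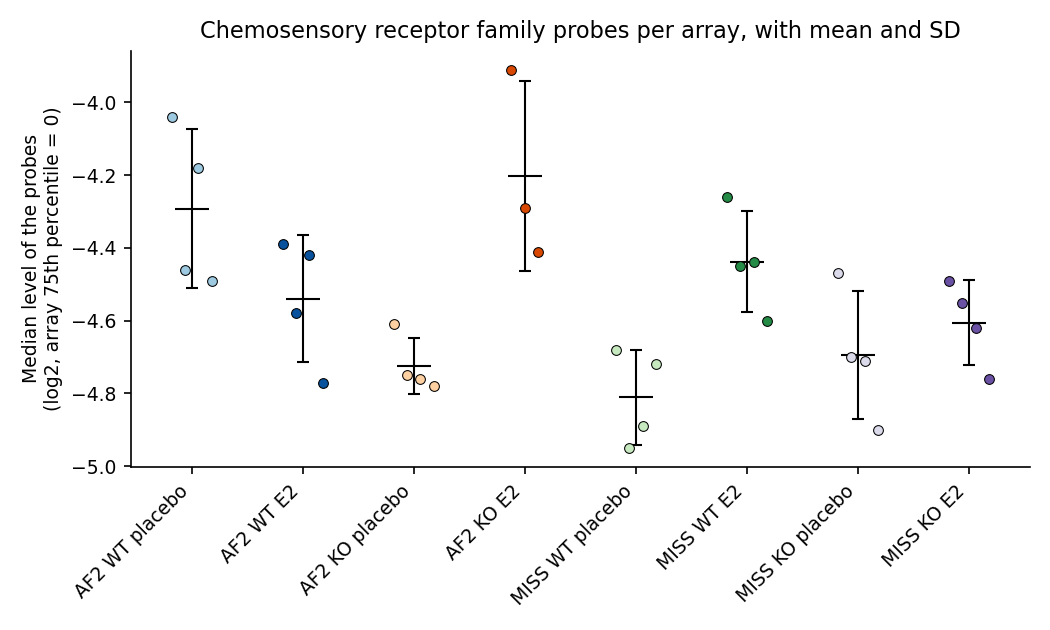
Median log2 level of the tested probes of chemosensory receptor families on each of the 31 arrays, relative to the array's 75th percentile, by group, with mean and SD. The group means run from −4.81 in MISS WT placebo to −4.20 in AF2 KO E2.

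The difference between the responses of AF2 KO and AF2 WT was tested directly. Gdf15, Krt87, Scube1 and Adamts4 had large negative differences, −9.14 ± 0.42, −7.84 ± 0.39, −7.23 ± 0.59 and −6.80 ± 0.43 (SE), and their changes in AF2 KO were −0.14, 0.20, −0.55 and −0.08, none called. Krt87 was above background on 1 of 3 AF2 KO E2 arrays. Fgf21 also responded less, but it was not above background in AF2 KO, so no size is given. Differences for Pgr, Greb1, Igf1 and Cdkn1a were −2.75 ± 0.16, −3.49 ± 0.66, −3.61 ± 0.19 and −3.85 ± 0.26. Positive differences were called for Tmc1, Slc22a22, Olfr911-ps1, Atp13a4 and Slco6b1, genes called lower with E2 in AF2 WT and higher in AF2 KO, whose sizes rest on signals near background. All 24 genes of ribosome biogenesis and 19 of 20 tRNA synthetases responded less in AF2 KO (24 and 19 adjusted over the list alone), with adjusted p = 1.78e-21 and 4.17e-14, and so did 20 of 28 estrogen-induced genes (20 lower and 1 higher adjusted over the list alone), with adjusted p = 7.99e-10. These 3 calls held at adjusted p = 0.00324, 0.00228 and 0.00831 with an estimated correlation, and on slides 1, 3 and 4 the medians for ribosome biogenesis were −2.07, −2.12 and −2.27. Lower responses in AF2 KO were also called for 16 of 18 immediate early genes, 16 of 20 ER chaperones, 15 of 18 genes of cholesterol synthesis and 9 of 19 cytokines, with 1 cytokine higher (17, 17, 16 and 9 lower and 1 higher adjusted over the list alone). Their medians were −2.24, −0.99, −1.89 and −0.92, and that of the cytokines was −1.83, −0.64 and −1.58 on slides 1, 3 and 4. Of 18 interferon-response genes, with 0 called in AF2 KO, 12 had a positive difference (13 adjusted over the list alone), with a median of 1.31, uneven at 0.13, 1.57 and 1.89 on slides 1, 3 and 4. These 5 lists were called at adjusted p = 6.77e-07, 9.03e-07, 1.16e-09, 0.0199 and 0.00277 and lost at adjusted p = 0.14, 0.131, 0.14, 0.517 and 0.633 with an estimated correlation. Of 27056 genes 14055 differed, 7846 more positive and 6209 more negative, with 6028 and 6035 under the strict filter, 4350 and 5602 without dim genes and 5581 and 6998 with the chemosensory covariate. Of the 12626 that were also called in AF2 WT, the change in AF2 KO was smaller in size for 11994, and 558 were called the opposite way in AF2 KO. These genes were chosen by calls on the same arrays, which favours a smaller change in AF2 KO. The median of all genes in this difference was 0.18, and 0.04 with quantile normalization, so values count from that shift.

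The response score put a number on the loss. It was 2.76 ± 0.122 (SD, n = 4) in AF2 WT and 0.141 ± 0.0584 (SD, n = 3) in AF2 KO, which is 5.09% of the wild type, over 4169 raised and 3808 lowered genes chosen in MISS WT. The difference of −2.62 gave p = 0.0286 by exact two-sided permutation, the smallest these 7 arrays allow. On slides 1, 3 and 4 the retained share was 5.8, 4.16 and 3.55%, and slide 2 has no AF2 KO E2 array. The small remainder depends on the processing, with 0.99% without dim genes, 1.24% with the authors' matrix, 1.57% with normexp correction and 9.75% with the chemosensory covariate, and −5.95% with genes chosen on the scored AF2 WT arrays. Of the 7977 chosen genes the 95% interval of the difference lay within 2-fold for 390 (4.89%). Of the same genes 6672 were called different, 6429 with a smaller and 243 with a larger response in AF2 KO. Of the genes called in both AF2 genotypes 37 were higher in both against 233.5 by independence, and 55 lower in both against 45.08. Opposite calls numbered 558 against 295.6, of which 498 were lower in WT but higher in KO. These 498 are among the 846 genes raised in AF2 KO, 600 of them dim, whose median change was 0.51 in MISS WT. Their fall in AF2 WT may rest in part on a raised signal on the AF2 WT placebo arrays. These counts therefore do not show a reversed action of E2.

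**Figure D3:**
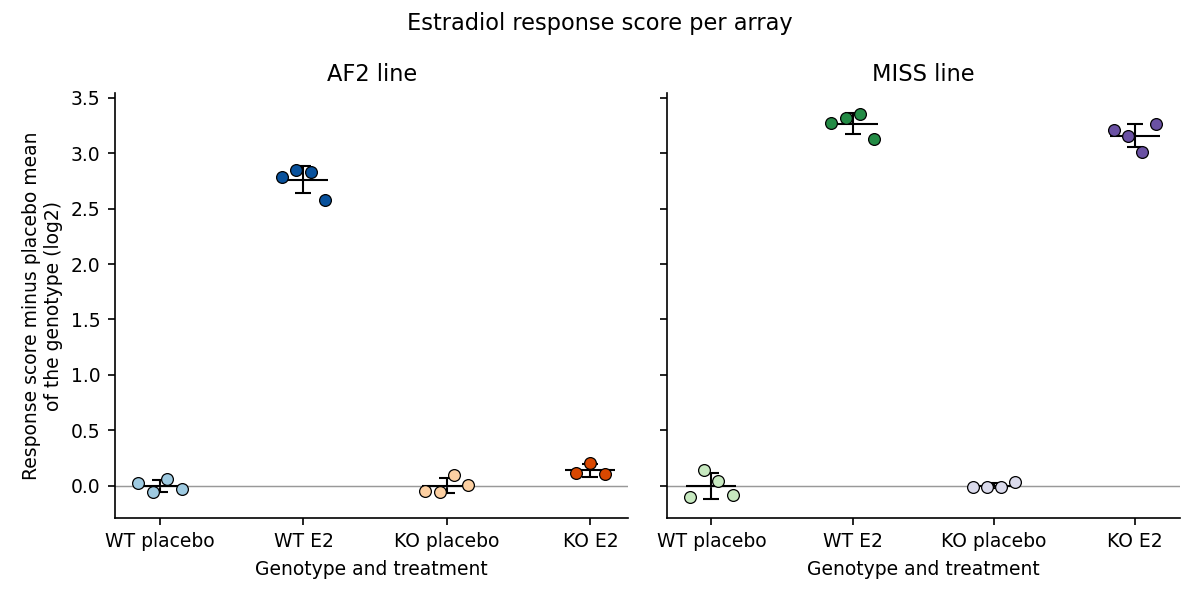
Response score (log2) of each array, by group, with mean and SD, for the genes chosen in the wild type of the other line. AF2 KO E2 arrays lie at 0.102 to 0.208 and AF2 WT E2 arrays at 2.58 to 2.85, while MISS KO E2 arrays lie at 3.01 to 3.26 and MISS WT E2 arrays at 3.13 to 3.35.

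Without hormone, AF2 KO uteri already differed from AF2 WT. Tmem213, a membrane protein gene on chromosome 6 (38065689 to 38065748), was lower by −5.65 ± 0.28, the ERα target Greb1 by −5.53 ± 0.45, the phosphatase subunit gene Ppp2r2c by −4.94 ± 0.24, the steroid reductase gene Akr1c14 by −4.13 ± 0.35 (SE, n = 4 and 4), and Prol1 at least 5.54-fold. Ltf was lower by −2.30 ± 0.46, adjusted p = 0.00166, and Pgr and Igf1 gave 0.23 ± 0.11 and 0.14 ± 0.13, not called. Higher in AF2 KO were Slc5a11 with 3.67 ± 0.50, Dlk1 with 3.17 ± 0.84, Ano2 with 3.30, and Bhmt2 and Tmem211 at least 3.88- and 3.12-fold. Of 17 epithelium markers 7 were higher and 1 lower (14 and 1 adjusted over the list alone), such as Krt8 with 0.78 ± 0.11, Tjp3 with 0.72 ± 0.15 and Esrp1 with 0.54 ± 0.08, and this list was called at adjusted p = 1.2e-09 and also at adjusted p = 0.0378 with an estimated correlation. Its medians on the 4 slides were 0.33, 0.56, 0.49 and 0.39. Of 14 progesterone targets 3 were higher (3 higher and 1 lower adjusted over the list alone), Cyp26a1 with 2.01, Lrp2 with 1.92 and Il13ra2 with 1.47, with adjusted p = 0.0135 and adjusted p = 0.41 with an estimated correlation. Interferon-response genes had a median of −0.58, 1 lower (7 adjusted over the list alone), and cytokines a median of −0.48, 3 lower (3 adjusted over the list alone), at adjusted p = 0.000283 and 0.0305. Adipocyte markers had a median of 1.27 with 0 of 10 called (0 adjusted over the list alone), at adjusted p = 0.0135. For these lists adjusted p = 0.668 with an estimated correlation. Of the 2447 genes called, 913 were higher and 1534 lower, 969 of the latter under a level of −2, and chemosensory families gave 63 lower and 1 higher. With slide as a block 5446 were called, and 1579 without AF2 WT placebo replicate 3; with quantile normalization 1231 were higher and 1146 lower.

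MISS WT mice, the control of the other line, gave a response of the same kind as AF2 WT. Trim15, Sprr2f, Myh7, Gdf15 and the kallikrein genes Klk1b26 and Klk1 rose most, by 8.02 ± 0.40, 7.99 ± 0.96, 7.82 ± 0.21, 7.48 ± 0.29, 7.36 and 7.35 ± 0.17 (SE, n = 4 and 4), and Pik3ip1 fell by 5.76 ± 0.22. Pgr, Greb1, Igf1 and Cdkn1a rose by 2.46 ± 0.11, 4.22 ± 0.45, 3.47 ± 0.13 and 3.87 ± 0.18. Again 24 of 24 genes of ribosome biogenesis and 19 of 20 tRNA synthetases rose, and 20 of 20 ER chaperones. Of 15 lymphocyte markers 8 were lower (7 adjusted over the list alone), with Cd3d at −1.81 ± 0.35, at adjusted p = 0.0412 and adjusted p = 0.687 with an estimated correlation. Their medians on slides 1 to 4 were −0.90, −1.93, −0.24 and −0.35, and their mean level varied under placebo, at 0.71 ± 0.62 (SD, n = 4, 0.20 to 1.53), against −0.07 ± 0.05 (SD, n = 4) with E2. Macrophage and interferon-response lists had medians of −0.55 and −0.86, which reversed on slide 4 at 0.11 and 0.43. Of the 26 lists 12 were called and 3 held with an estimated correlation, ribosome biogenesis, tRNA synthetases and estrogen-induced genes, at adjusted p = 0.0144, 0.011 and 0.0202. In total 16842 genes were called, 9500 higher and 7342 lower, with a median of all genes of 0.16, and 0.06 with quantile normalization. The split under quantile normalization was 8502 higher and 8549 lower. Of the genes called in both wild types, 6805 rose in both against 2621 by independence, 6116 fell in both against 2206, and 317 went opposite ways against 4881. The correlation of the changes across genes, which are not independent replicates, was 0.844.

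MISS KO mice kept this response. Tmem213 rose by 8.24 ± 0.28, Scube1 by 8.05 ± 0.40, Sprr2f by 7.83 ± 0.96, Myh7 by 7.44 ± 0.21 and Gdf15 by 7.04 ± 0.29 (SE, n = 4 and 4), Fgf21 rose at least 32.6-fold, and Pik3ip1 fell by 5.50 ± 0.22. Pgr, Greb1, Igf1 and Cdkn1a rose by 2.58 ± 0.11, 5.63 ± 0.45, 3.55 ± 0.13 and 3.51 ± 0.18. Ribosome biogenesis rose with 24 of 24 genes (24 adjusted over the list alone), a median of 2.09 and adjusted p = 1.96e-17, tRNA synthetases with 19 of 20 (19) and adjusted p = 4.29e-12, and estrogen-induced genes with 23 of 28 higher and 1 lower (23 and 1) and adjusted p = 3.81e-10. With an estimated correlation these gave adjusted p = 0.00721, 0.00563 and 0.00721, and the other 5 of the 8 lists called were lost. In total 15512 genes were called, 8140 higher and 7372 lower, but 7690 higher and 8027 lower with quantile normalization. Of genes called in both MISS genotypes 7470 rose in both against 2858 by independence, 6311 fell in both against 2000, and 31 went opposite ways.

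**Figure D4:**
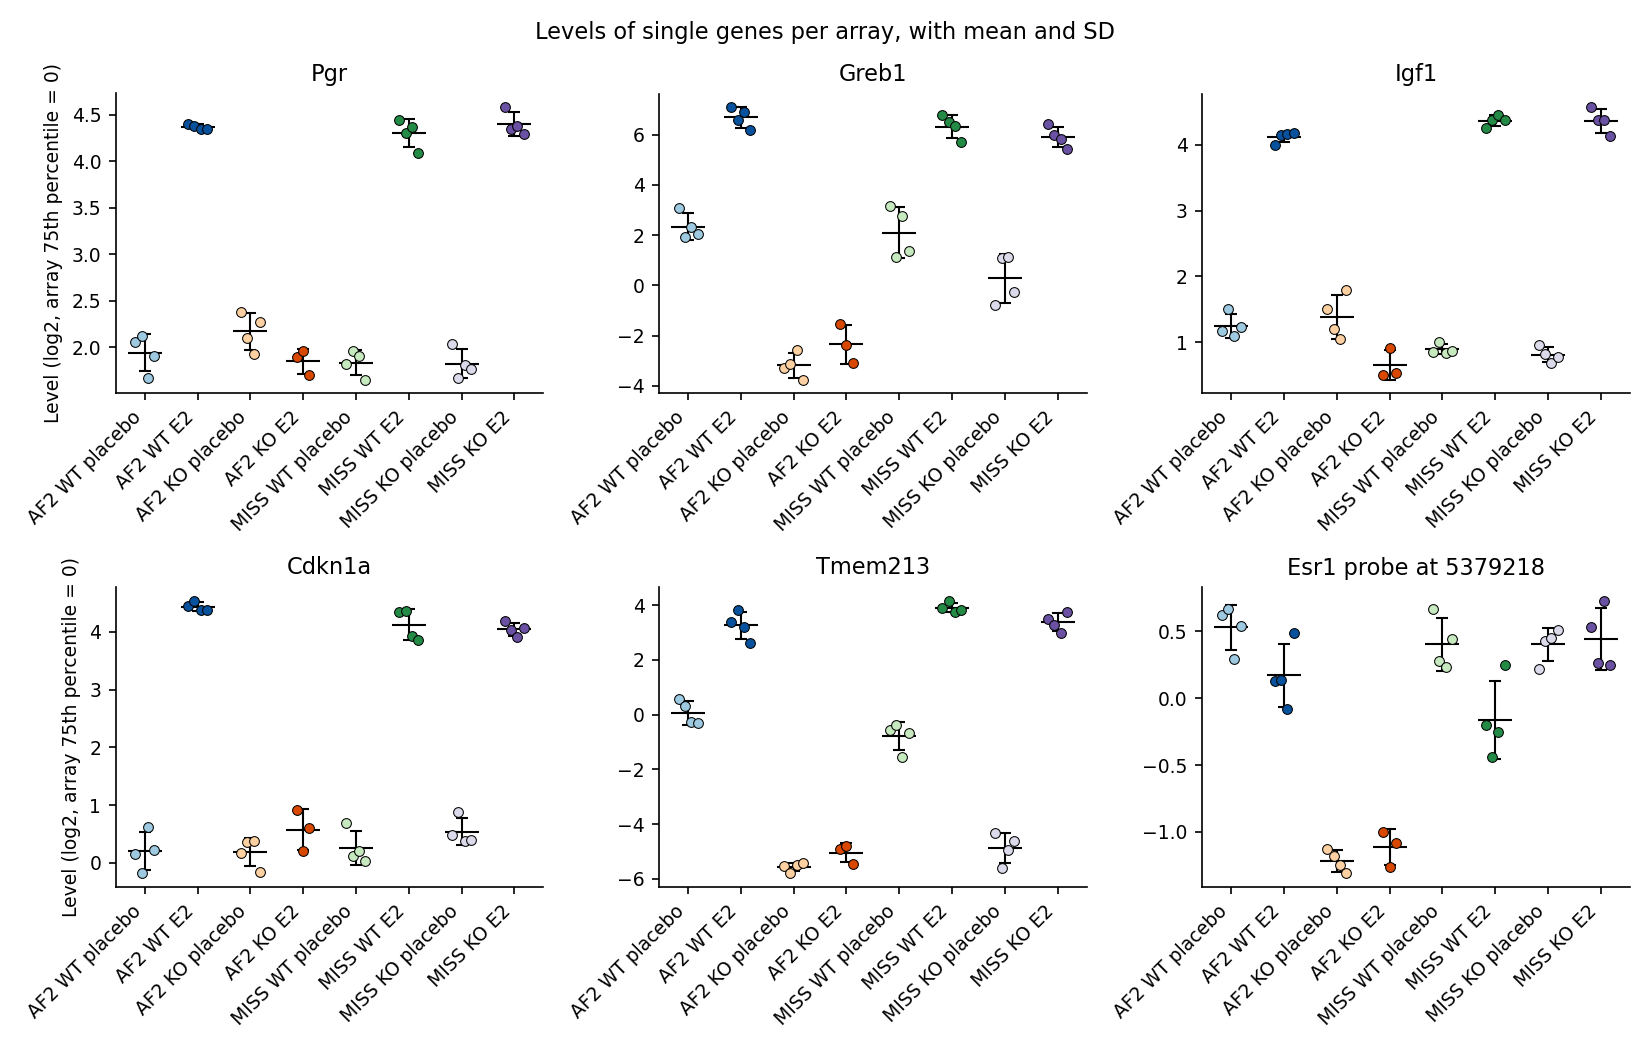
Level (log2 relative to the array's 75th percentile) of Pgr, Greb1, Igf1, Cdkn1a, Tmem213 and the Esr1 probe at 5379218 on each array, by group, with mean and SD. Pgr stands at 1.85 ± 0.14 in AF2 KO E2 against 4.37 ± 0.03 in AF2 WT E2 and 4.40 ± 0.13 in MISS KO E2.

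Few responses were called different between MISS KO and MISS WT when the difference was tested. Tmem213 rose more in KO by 3.55 ± 0.39, from a placebo level lower by −4.08 ± 0.28 (SE). Gli1, a transcription factor of the hedgehog pathway, rose in MISS KO by 1.85 ± 0.33 and gave −0.29 ± 0.33 in MISS WT, and Oit1, Tmem119 and Dleu7 had differences of 1.94, 1.63 and 1.62. Mdga1 rose in MISS WT by 3.32 ± 0.29 and gave 0.30 ± 0.29 in MISS KO, and Slc9a2 and Col26a1 also responded less in KO, by −2.75 and −2.71. Fam163a rose less in KO, and Disp2 was called higher in MISS WT but lower in MISS KO; neither was above background in MISS KO E2, so no size is given. In total 243 genes were called different, 66 more positive and 177 more negative (87 and 147 with quantile normalization). The count was 1119 with slide as a block and 1812 with array weights. It was 160 without MISS KO placebo replicate 1 and 138 without MISS WT placebo replicate 3. In simulations this contrast recovered 21.7% of genes changed 1.5-fold and 59.6% of those changed 2-fold, so smaller differences can be missed. ER chaperones responded less as a list, with a median of −0.29 and 2 of 20 called (5 adjusted over the list alone), adjusted p = 2.33e-05, but adjusted p = 0.704 with an estimated correlation. Another 7 lists were called by small medians of −0.14 to 0.53 and lost at adjusted p = 0.76 with an estimated correlation: ribosome biogenesis lower, and mitosis, cholesterol synthesis, interferon response and markers of smooth muscle, macrophages and lymphocytes higher. The response score was 3.27 ± 0.0982 (SD, n = 4) in MISS WT and 3.16 ± 0.107 (SD, n = 4) in MISS KO, 96.7% retained, exact two-sided permutation p = 0.2 where 0.0286 is the smallest possible. Within the 4 slides 95.7, 99.8, 91.3 and 100% was retained. With genes chosen in MISS WT itself the share was 88.7%, exact permutation p = 0.0286, but that choice on the scored arrays raises the wild-type score and so lowers the share even where the genotypes do not differ. Of 6896 genes the 95% interval of the difference lay within 2-fold for 4497 (65.2%), and 101 were called different.

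**Figure D5:**
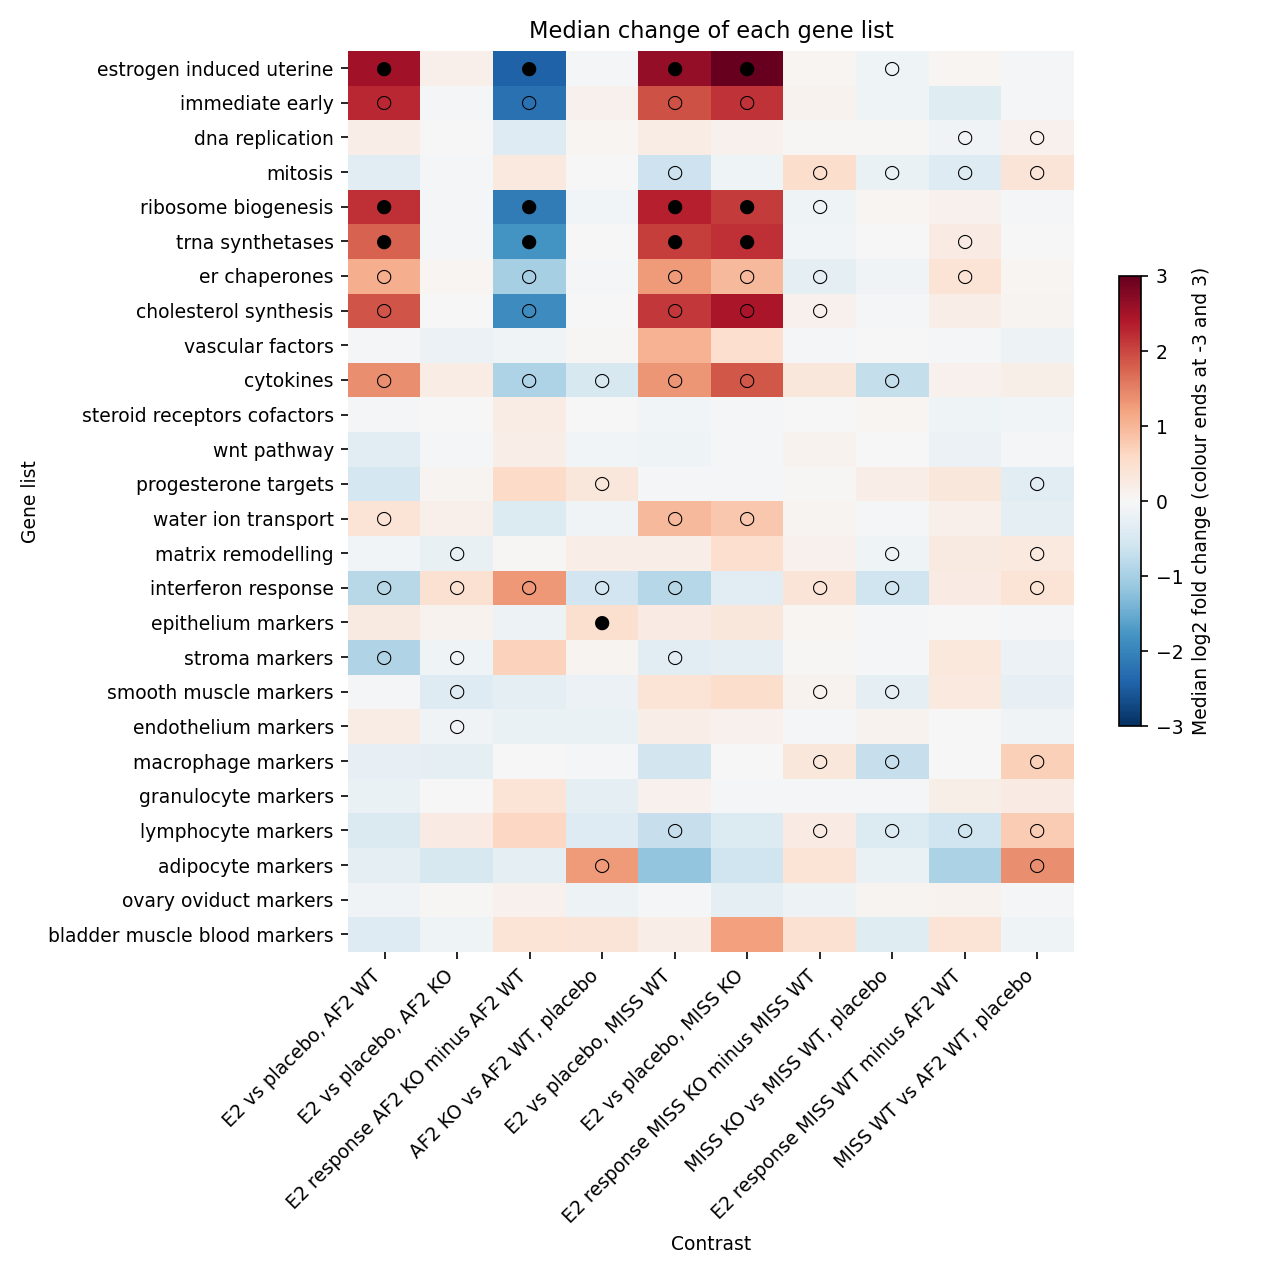
Median log2 fold change of each of the 26 gene lists in each of the 10 contrasts, as colour from −3 to 3. Open circles are lists called with the preset correlation alone and filled circles lists also called with an estimated correlation, such as ribosome biogenesis with a median of 2.20 in AF2 WT and 2.09 in MISS KO.

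Under placebo, few genes were called between MISS KO and MISS WT, and part of them were shared with AF2 KO. Tmem213 was lower by −4.08 ± 0.28, Akr1c14 by −3.39 ± 0.35 and Asb4 by −2.31 (SE, n = 4 and 4), and Klk1b27 and Ugt2b34 were at least 2.73- and 2.64-fold lower. Higher were the cardiac myosin gene Myh6 with 3.07 ± 0.55, Pde6h with 2.54, Brinp1 with 2.41, and Sox2ot at least 1.95-fold, where Myh6 varied between MISS WT placebo arrays with an SD of 1.99. Greb1 gave −1.81 ± 0.45 with adjusted p = 0.0501 and was not called. The immune lists had lower medians, of −0.60 for interferon response (1 called, 8 adjusted over the list alone), −0.70 for macrophage markers (0 and 9), −0.40 for lymphocyte markers (0 and 5) and −0.71 for cytokines (1 and 4), at adjusted p = 1.46e-13, 4.96e-08, 1.26e-05 and 7.97e-06. With an estimated correlation these gave adjusted p = 0.172, 0.172, 0.256 and 0.172. On slides 1 to 4 the lymphocyte medians were −0.74, −1.60, 0.09 and −0.04 and the macrophage medians −0.55, −1.65, −0.70 and −0.01, so both were uneven. Mitosis, estrogen-induced genes, smooth muscle markers and matrix remodelling, with medians of −0.20, −0.12, −0.26 and −0.14, were called at adjusted p = 4.46e-05, 0.000883, 0.000216 and 0.0458 and lost at adjusted p = 0.332, 0.256, 0.486 and 0.486 with an estimated correlation. In total 230 genes were called, 108 higher and 122 lower. With slide as a block 481 were higher and 358 lower, with array weights 1212 and 699, and with the compared groups alone 3 and 15. The count was 119, 59 and 672 without MISS WT placebo replicates 1, 3 and 4, and 99, 110, 139 and 146 without MISS KO placebo replicates 1, 2, 3 and 4. Of genes called in both mutants under placebo 76 were lower in both against 6.92 by independence, 51 higher in both against 3.64, and 1 opposite against 10.2. Tmem213, Akr1c14, Ppp2r2c (−4.94 in AF2 KO, −1.95 in MISS KO) and the oxytocin receptor gene Oxtr (−1.38 and −1.55) were among those lower, and Myh6 (2.76 and 3.07) and Cyp1b1 (1.18 and 1.89) among those higher; these shared genes were picked after their values were seen.

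The wild types of both lines differ in substrain and line and may differ in cohort, which the design cannot separate. Nnt, a mitochondrial transhydrogenase gene deleted in part in C57BL/6J mice, was higher in MISS WT than in AF2 WT placebo by 1.04 ± 0.09 (SE, n = 4 and 4), adjusted p = 6.23e-08 over 40332 probes, at its brightest probe, while its other tested probes were not called. Erdr1 was lower in MISS WT by −6.30 ± 0.66, and Pramel48, Afm, Slco6b1 and Tmc1 were at least 14.5-, 8.79-, 7.37- and 5.51-fold lower. Higher were Ubd at least 3.95-fold, Igh-VJ558 with 2.66, Scgb1b29 with 2.55, and Skp1a and Glycam1 at least 1.57- and 1.18-fold; with normexp correction Skp1a gave −0.00. Macrophage markers were higher, 5 of 12 with 1 lower (9 and 1 adjusted over the list alone), such as C1qa with 1.14 ± 0.30 and Cd68 with 0.78 ± 0.19, and lymphocyte markers, 5 of 15 (9), such as Cd3d with 1.40 ± 0.35. Interferon-response genes were higher too, 3 of 18 (5 higher and 1 lower adjusted over the list alone), with 1.23 ± 0.24 for Gbp2. These lists gave adjusted p = 7.59e-05, 9.91e-06 and 3.16e-05, and adjusted p = 0.491, 0.491 and 0.547 with an estimated correlation. On slide 4 their medians were 0.03, 0.03 and −0.12, against 0.33 to 1.38 on the other slides. Adipocyte markers had a median of 1.40 with 0 of 10 called, at adjusted p = 0.00426 (adjusted p = 0.741 with an estimated correlation). Of 3153 genes called, 823 were higher and 2330 lower, 1430 of the latter under a level of −2, and 105 chemosensory genes were lower and 2 higher. With quantile normalization 1395 were higher and 1957 lower. Lists of mitosis, DNA replication and matrix remodelling were also called higher and progesterone targets lower, at adjusted p = 5.17e-05, 0.00426, 0.0196 and 0.0239, and lost at adjusted p = 0.491, 0.542, 0.56 and 0.491 with an estimated correlation. The count was 5650 with slide as a block, 1437 without dim genes and 1932 without AF2 WT placebo replicate 3.

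The E2 responses of both wild types also differed. Igf1 rose more in MISS WT by 0.60 ± 0.18 (SE), adjusted p = 0.0317, and Chac1, an enzyme that degrades glutathione, rose less, by 3.45 ± 0.24 against 6.37 ± 0.24 in AF2 WT, a difference of −2.91 ± 0.35. Trhde fell more in MISS WT, with a difference of −2.75, and Nsg2, with −2.82, had another probe at 0.39 that disagrees. Caps2 and Sox1ot also fell more, to levels not above background, and another Sox1ot probe at 0.19 disagrees. Pramel48, Tmc1, Slco6b1, Mei4 and Atp13a4 had positive differences, whose sizes rest on signals near background in MISS WT placebo. Of 20 ER chaperones 7 rose more in MISS WT (8 adjusted over the list alone), median 0.40, at adjusted p = 0.00258 and adjusted p = 0.608 with an estimated correlation. The tRNA synthetases were also called higher, and DNA replication, mitosis and lymphocyte markers lower, at adjusted p = 0.0471, 0.0278, 0.00258 and 0.00258, all lost at adjusted p = 0.608 with an estimated correlation. Differences were called for 2571 genes, 1730 positive and 841 negative, and for 5821 with slide as a block. The median of all genes was 0.11, and 0.00 with quantile normalization, where 1054 were positive and 1099 negative. Without dim genes 1672 were called.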

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

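The tests of the scaling, of E2 acting in the AF2 mutant and of a lower share of other cell types were chosen only after the result was seen.

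Dim genes were higher in AF2 KO E2 than in AF2 KO placebo, and the chemosensory receptor families, outside the report's lists, were well above background for 32.3% of their probes against 21.3%. Scaling each array to its 75th percentile stays open. Without it the 846 higher genes still had a median difference of 0.81, against 1.13 with it, but they were chosen by the call on these arrays, so that value excludes nothing. All 10633 tested genes of a mean level under −2, not chosen by the call, differed by 0.26 ± 0.07 (SE) with scaling and by −0.05 ± 0.16 without it. The other 16423 genes differed by −0.02 ± 0.02 and −0.34 ± 0.17 (SE). Dim genes thus rose relative to the others. Scaling subtracts the same value from every gene of an array and cannot change that gap, so the gap does not test the scaling. Without scaling the dim genes themselves showed no rise beyond the SE. Genomic DNA or another signal without strand stays open. Over 1067 intervals with probes on both strands, the dimmer strand was higher by a median of 0.27 and the brighter by 0.12, both with the scaling. The mean log2 75th percentile was 9.20 in AF2 KO E2 and 9.52 in AF2 KO placebo, a gap larger than either rise. Medians of the dimmer strand per array averaged −3.84 and −4.14 in these groups (SE of the difference 0.11). They also rose with E2 in MISS WT, from −4.20 to −3.94. E2 acting in the mutant cannot be told apart from a signal without strand, since the 846 higher genes changed by −0.69 in AF2 WT but by 0.51 in MISS WT and 0.31 in MISS KO. The bound of −0.5 set on that value does not hold if the AF2 WT placebo arrays carry the raised signal too. On arrays that took no part in the call, the median of these genes was lower in MISS WT than in AF2 WT placebo. MISS KO and MISS WT placebo differed by 0.11, but the lines also differ in substrain and may differ in cohort.

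The macrophage, lymphocyte and interferon lists had higher medians in MISS WT placebo than in AF2 WT placebo and MISS KO placebo. Against AF2 WT 5 of 12, 5 of 15 and 3 of 18 genes were called higher, and against MISS KO 0, 0 and 1. None of these lists was called with an estimated correlation, at adjusted p = 0.491, 0.491 and 0.547 against AF2 WT and 0.172, 0.256 and 0.172 against MISS KO. A single array rich in immune cells is argued against as the whole cause of the macrophage difference from AF2 WT. The macrophage median of 0.72 stayed at 0.51 or more with any 1 MISS WT placebo array left out, although within slides it ran from 0.03 to 1.38. The lymphocyte and interferon lists and the comparison with MISS KO were not tested this way. A lower share of other cell types stays open. The endothelium markers had a median of −0.10 and the adipocyte markers 1.40, so these lists disagreed and the test cannot decide. More immune cells in these uteri, or a difference of substrain, line or cohort, stays open and was not tested.

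Single arrays far from the others of their group, by Dixon's test, were 10 in 105 sets, where chance gives about 1 in 20, or 5.2. The AF2 KO E2 group, with only 3 arrays, was not screened by this test. Esr1 stood at 3.65 in AF2 WT E2 replicate 4 (others 3.03 to 3.14) and at 2.84 in MISS KO E2 replicate 2 (3.36 to 3.41). C3 stood at 7.86 in MISS WT placebo replicate 2 (6.86 to 6.99) and at 5.95 in MISS KO placebo replicate 3 (6.77 to 6.81), and Nnt at 3.05 in MISS WT E2 replicate 4 (2.80 to 2.84). The mean of the epithelium markers was 2.30 in AF2 KO placebo replicate 4 (2.36 to 2.37) and 1.90 in MISS KO placebo replicate 1 (1.73 to 1.74), and that of the endothelium markers 2.45 in MISS KO E2 replicate 2 (2.20 to 2.23). The mean of the adipocyte markers was −0.91 in MISS WT placebo replicate 1 (1.42 to 1.80). The score genes of the MISS line, before placebo was subtracted, stood at 1.27 in MISS KO placebo replicate 4 (1.22 to 1.23).

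Differences between groups passed their own tests in these cases. The E2 response differed between AF2 KO and AF2 WT for 14055 genes, between MISS KO and MISS WT for 243, and between MISS WT and AF2 WT for 2571. In the AF2 line the response score differed by −2.62, Pgr by −2.75, Greb1 by −3.49, Igf1 by −3.61, Cdkn1a by −3.85 and Nnt by 0.35. Igf1 rose more in MISS WT than in AF2 WT by 0.60.

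For each count of genes, 1 of the splits tried, the real one, gave as many genes, among splits that ignore the slide. That argues against chance for each count taken alone but does not exclude it. The shares were not adjusted over the contrasts, and these splits mix arrays of different slides. Splits that exchange arrays within slides number 8 for each comparison of 2 groups, too few for a share under 0.05, and the highest of the others gave 256 genes; for the differences of responses none was drawn. For 35 splits each, the real value and the highest of the others were 15597 and 5132 for E2 in AF2 WT, 996 and 41 in AF2 KO, 16842 and 7346 in MISS WT, and 15512 and 4 in MISS KO. Under placebo they were 2447 and 5 for AF2 KO against AF2 WT, 230 and 26 for MISS KO against MISS WT, and 3153 and 1028 for MISS WT against AF2 WT. For the differences of responses, with 100 splits drawn, they were 14055 and 8798 in the AF2 line, 243 and 144 in the MISS line, and 2571 and 1485 between the wild types.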

How the results depend on the processing

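The fits without dim genes and with the chemosensory level as a covariate were added only after the result was seen. Of 440 counts under an alternative, 386 stayed within 1.5 times the reported count. Below, the contrasts are E2 in AF2 KO (KO-E2), AF2 KO against WT placebo (AF2-placebo), MISS KO against WT placebo (MISS-placebo), MISS WT against AF2 WT placebo (line-placebo), the MISS difference of responses (MISS-difference) and the wild-type difference (line-difference). With slide as a block the counts were 2770 (KO-E2), 5446 (AF2-placebo), 839 (MISS-placebo), 5650 (line-placebo), 1119 (MISS-difference) and 5821 (line-difference); array weights gave 1805, 4501, 1911, 5642, 1812 and 4560. A minimum of 2-fold, which removes smaller changes by construction, gave 502, 965, 90, 1409, 120 and 1146, and 6896 for E2 in AF2 WT, 7977 in MISS WT, 7045 in MISS KO and 7927 for the AF2 difference. The compared groups alone, with fewer arrays, gave 325 (KO-E2), 18 (MISS-placebo), 1326 (line-placebo), 153 (MISS-difference) and 1648 (line-difference). Normexp correction gave 1672 (KO-E2), 3943 (AF2-placebo) and 5413 (line-placebo), and the fit without dim genes, with fewer genes, 310, 1304 and 1437, and 1672 (line-difference). KO-E2 was 643 with quantile normalization, 589 with the strict filter and 327 with the covariate, and MISS-placebo 375 with the authors' matrix.

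With 1 array left out, counts ran from 239 (without AF2 KO E2 replicate 1) to 1107 for KO-E2, 1579 (without AF2 WT placebo replicate 3) to 2782 for AF2-placebo, 59 (without MISS WT placebo replicate 3) to 672 (without MISS WT placebo replicate 4) for MISS-placebo, 1932 (without AF2 WT placebo replicate 3) to 3607 for line-placebo, 138 (without MISS WT placebo replicate 3) to 354 for MISS-difference and 1875 to 2849 for line-difference. They ran from 14785 to 15752 for E2 in AF2 WT, 15768 to 16998 in MISS WT, 14827 to 15650 in MISS KO, and 12917 to 14263 for the AF2 difference. The retained score ran from 3.81 to 6.46% in the AF2 line, where 7 of these settings have too few arrays for an exact p under 0.05, and from 95.3 to 98.2% in the MISS line. Under the other alternatives for scaling, filter and fit the AF2 score ran from 0.99 (without dim genes) to 9.75% (with the covariate). With genes chosen in its own wild type the AF2 score was −5.95% retained, and the MISS score was 88.7% retained, exact permutation p = 0.0286. This choice is made on the scored arrays and raises the wild-type score by construction. A raised wild-type score lowers a share but cannot make it negative, so with these genes the AF2 KO score itself was negative. The larger of the higher and lower counts changed sides in the settings given here, higher before lower. For the AF2 difference these were 6028 and 6035 (strict filter), 4350 and 5602 (without dim genes) and 5581 and 6998 (covariate). For E2 in AF2 WT they were 7244 and 7129 (normexp), 7098 and 6487 (strict filter), 6260 and 4949 (without dim genes) and 8165 and 7573 (covariate). With quantile normalization and the authors' matrix they were 8502 and 8549, and 8319 and 8503, for E2 in MISS WT, and 7690 and 8027, and 7539 and 7898, in MISS KO, where at least 2-fold gave 3501 and 3544. For AF2-placebo they were 1231 and 1146 (quantile), 1252 and 1215 (authors' matrix), 728 and 576 (without dim genes) and 1233 and 800 (covariate). For MISS-placebo they were 162 and 150 (normexp), 481 and 358 (block), 1212 and 699 (weights) and 119 and 112 (without dim genes). For line-difference they were 1054 and 1099 (quantile) and 1267 and 1436 (covariate), and for line-placebo 1328 and 1205 (covariate). Interferon-response genes in the line-difference gave 0.58 with the covariate, with the test's direction reversed against a median of 0.24, Pycr1 0.08 with the strict filter and Skp1a −0.00 with normexp. Of 11180 list values 10860 kept direction and call, 168 lost and 151 gained the call, and of 51659 gene values 49853 kept both. Unless construction shows it, the cause was not tested. Signal over background limits the dim genes, 600 of the 846 raised in AF2 KO.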

Other observations

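The counts of called genes under the hypothesis in this part, and the genes named outside the fixed rule, were chosen only after the result was seen, while both medians were planned before.

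Cell-cycle genes went both ways 6 h after E2. In AF2 WT, MISS WT and MISS KO, the replication gene Pcna rose by 1.38, 1.57 and 1.48, and the checkpoint gene Mad2l1 by 5.43, 4.79 and 4.38. The checkpoint kinase gene Bub1b gave −2.17, −2.60 and −2.08 and the centromere gene Cenpa −1.86, −2.19 and −1.97, all called. Of 23 genes of DNA replication 9 rose and 3 fell in AF2 WT, adjusted p = 0.195 by limma's camera, and of 17 mitosis genes 2 rose and 7 fell, adjusted p = 0.473. The mitosis list was called in MISS WT, 2 higher and 10 lower, at adjusted p = 0.0353, with adjusted p = 0.687 with an estimated correlation.

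Signalling genes also moved in opposite ways within their lists, none of which camera called in AF2 WT. Of 13 vascular factors 5 rose and 6 fell, with Vegfa at 3.97 ± 0.13 (SE) and Pgf at 5.45 against Vegfc at −1.94. Of 20 Wnt pathway genes 6 rose and 9 fell, with Wnt4 at 3.71 and Wnt7b at 3.49 against Sfrp2 at −1.62. Of 20 matrix remodelling genes 5 rose and 7 fell, with the hyaluronan synthase gene Has1 at 6.08 against the protease gene Mmp11 at −3.03. Of 18 steroid receptors and cofactors 5 rose and 6 fell, with Nrip1 at 2.23, and of 14 progesterone targets 2 rose and 7 fell, with Hoxa10 at −1.29. The adjusted p values were 0.882, 0.88, 0.967, 0.88 and 0.167.

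A hypothesis was that the receptor acts without E2 through activation function 2, so that genes raised by E2 would be lower in AF2 KO placebo than in AF2 WT placebo. The gap between the medians of genes lowered and raised by E2 in MISS WT was 0.04, 0.02 to 0.06 with 1 array left out, so no common shift of these genes was seen. The bound of 0.1 set on that gap was wrong, because called members went both ways and leaned with the hypothesis: of 4169 raised genes 347 were lower and 91 higher in AF2 KO placebo, and of 3808 lowered genes 112 were lower and 265 higher. Over all 27056 tested genes 1534 were lower and 913 higher, so the whole contrast leaned lower too. Greb1 with −5.53 and Tmem213 with −5.65 are among the lower ones, and of 28 estrogen-induced uterine genes 7 were lower and 3 higher, with adjusted p = 0.699 by camera. Extra signal on dim genes in AF2 WT placebo was the technical alternative. Among genes above the 75th percentile the gap was 0.03, and 62 of 2329 raised genes were lower and 44 higher, while of 1240 lowered genes 23 were lower and 101 higher. With no gap to explain, that test decides nothing, and whether part of these genes depends on the receptor without E2 stays open.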
